A study of Mus musculus with 6 samples.

How the data were processed

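Total RNA of 6 cultures was labelled with biotin by a terminal transferase kit for whole-transcript arrays, per the labels' protocols, and hybridised to 1 array each. The samples were grouped by their titles as control or Brg1 KO (3 arrays per group) of the cell lines B1, B2 and B11. Per the labels' protocols the cells received 4-hydroxytamoxifen or methanol for 5 days, whereas the series' design text gives 4 days. In the source labels of the KO arrays of B2 and B11 the deleted gene carries another number than in their titles and treatment labels, and the titles were followed. Nothing says whether further cultures of a line were made, so p-values measure the spread between these 3 lines and their cultures.

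The deposited table holds log2 values per probe set. The log base is taken from the range of the values, and the software, background correction and normalization behind them are not given in the sources used here. The deposited log2 values run up to 19.28, and 204 to 255 probe sets per array lie above 16, the log2 maximum of a 16-bit scanner. They are therefore not plain log2 scanner readings, for a reason that is not given, and fold changes hold on the deposited scale only. The medians of the arrays lay between 5.64 and 5.75 and the upper quartiles between 9.93 and 10.03. No scanner files were used and no background flags came with the values, so no probe set could be called undetected; the number of arrays limits the precision.

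Of the 22206 probe sets, 19572 were paired with 1 gene symbol by the platform annotation, 0 with several, and 2634 were not listed and stay unnamed. All 19572 matched by Entrez identifier a RefSeq gene table of mouse assembly GRCm38.p6, which changed 0 symbols. The build of the array design is not named, so no coordinates are given. Where a symbol had several probe sets, the one with the highest mean over all 6 arrays was kept, leaving 19505 genes, with no filter on dim genes.

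Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05 over all genes). The fit has the group alone, since no source states a paired test. The line names pair the arrays: arrays of the same line deviated together from their group means, with correlations across genes of 0.73 for B1, 0.55 for B2 and 0.47 for B11, and the pairs share a named cell line. The fit with the line as a block was therefore set beside the results it changes, as for the gene count, which went from 0 to 30. With 3 arrays against 3, an exact permutation test cannot give a two-sided p below 0.1.

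Before the data were examined, 39 gene lists with 848 entries (783 distinct genes) were fixed, covering hypoxia and the HIF pathway, metabolism, stem cell and invasion genes, states of pancreatic cells, markers of other cell types, the cell cycle, signalling outputs, stress responses and genes that 4-hydroxytamoxifen or Cre could affect. Of the distinct genes, 723 were measured and 60 had no matching symbol. Lists were tested with limma's camera at its preset correlation of 0.01, adjusted over the 39 lists, with an estimated correlation and with fry as alternatives; fry tests whether the genes of a list move one way on balance, not against other genes. Member calls were counted over all genes and adjusted over the list alone. A result of a list over genes rests on correlated members, which are not independent replicates.

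The genes named in the text were chosen by a rule fixed in advance. It took Smarca4, Smarca2, Hif1a and Epas1 whatever their values. It took the 12 largest rises and the 12 largest falls past the threshold with the same direction in all 3 lines, filled from the fit with the block where the fit without it gave none (as it did for all 24 places) and then by the lowest p, and left out predicted genes. From each list it took up to 4 members with the largest change in the same direction in all 3 lines, of which the text gives some. Members outside the rule are said to have been named after their values were seen.

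The alternatives were the line as a fixed or random block (duplicateCorrelation), quantile normalization, centring on the median, genes above the median level only, the mean of probe sets, trend and robust variance, every probe set, a threshold of 0.1, a 2-fold minimum, and leaving out each array or each pair. When an array is left out without a block, the remaining spread is pooled over both groups. Cyclic loess, and each choice combined with the block, were added after seeing the data.

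The steps were tested on simulated data with the real gene means, line differences and residual spread (20 simulations of 19505 genes, 200 of them changed). Without the block, limma recovered 4.48% of genes changed by 1 log2 unit, 50.8% of those changed by 2 and 84.8% of those changed by 4. With the line as a block it recovered 0.746%, 44.1% and 80.8%. The real data gave 0 genes without the block and 30 with it. The simulated genes were drawn independently of each other and the changed ones at random. These rates therefore do not say what share of the real changes was found. False calls were 1.17% and 2.28% of all calls, and a list of 40 independent genes shifted by -0.60 was called in 20 of 20 simulations. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.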

Results

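The expression of Brg1-deficient pancreatic cancer cells was measured on 6 microarrays of total RNA. The cells were the mouse pancreatic ductal adenocarcinoma lines B1, B2 and B11, established from tumours of mice in which a Flp recombinase under the Pdx1 promoter switched on oncogenic Kras and removed an allele of Trp53. They also carried a tamoxifen-inducible Cre recombinase and loxP-flanked alleles of Brg1 (gene symbol Smarca4), the ATPase of the SWI/SNF chromatin remodelling complex. Each line gave 1 array after 4-hydroxytamoxifen, which activates Cre and deletes Brg1 (Brg1 KO, n = 3), and 1 array after the solvent methanol (control, n = 3). The comparison asks which genes differ once Brg1 is removed, with the hypoxia pathway, stemness and metastasis named in the title of the series. All 6 arrays covered 22206 probe sets with closely matching medians, from 5.64 to 5.75 on the deposited log2 scale, and 19505 named genes were tested. No array received 4-hydroxytamoxifen without the floxed Brg1 alleles, so an effect of the drug or of Cre is part of every difference given here.

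Smarca4 itself was lower in all 3 lines after 4-hydroxytamoxifen. Its level (probe set TC0900000203.mm.2) was 12.21 ± 0.92 (SD, n = 3) in control cells and 8.08 ± 1.39 (SD, n = 3) in KO cells, a log2 change of -4.14, or 17.6-fold lower. The array values went from 11.35 to 7.44 in B1, from 13.19 to 9.67 in B2 and from 12.10 to 7.12 in B11, so that B2 kept the highest remaining signal. Where the probes lie relative to the deleted exons is not given in the sources used here. Smarca2 (Brm), the alternative ATPase of the complex, differed by 0.19 with an SE of 0.46 and did not pass (limma adjusted p = 0.988). Hif1a and Epas1 encode oxygen-regulated subunits of the hypoxia-inducible factors. They differed by -0.39 with an SE of 0.27 and by -0.34 with an SE of 0.74, and neither passed (limma adjusted p = 0.873 and 0.987). With the cell line as a block the SE was 0.27 for Smarca2, 0.27 for Hif1a and 0.21 for Epas1. None of them passed in that fit either (limma adjusted p = 0.826, 0.585 and 0.539). Without the control array of B2 the change of Smarca2 was -0.25, and without the control array of B11 that of Epas1 was 0.29. Hif1a was lower in B1 and B11, by -0.42 and -0.96, and higher in B2, by 0.21. In limma without the cell line as a block, the fall of Smarca4 had an adjusted p of 0.396; with the cell line as a block, which takes the paired difference within each line, it had an adjusted p of 0.0477 at the log2 change of -4.14.

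**Figure D1:**
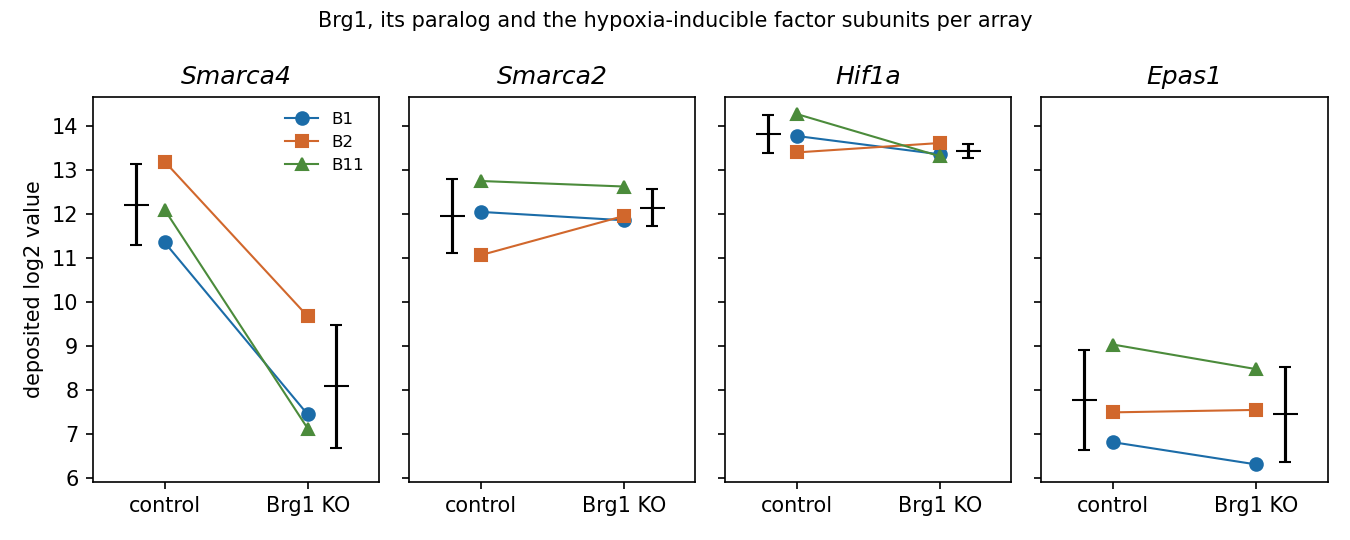
Deposited log2 values of Smarca4, Smarca2, Hif1a and Epas1 on each array (vertical axis) in control and Brg1 KO cells (horizontal axis), with a line joining the 2 arrays of each cell line and black bars for the group mean ± SD (n = 3). Smarca4 drops in each line by 3.52 or more, while the other 3 genes go different ways in different lines.

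The genes that passed limma with the cell line as a block and went the same way in all 3 lines were headed by Syt11, a synaptotagmin of vesicle traffic, which rose from 8.96 ± 0.59 to 13.02 ± 0.74 (SD, n = 3), a log2 change of 4.06. The growth factor Tgfb3 rose by 3.48 and Ppp1r14a, an inhibitor of myosin phosphatase, by 3.26. Fitm2, which acts in lipid droplet formation, rose by 3.16, Tmem150a by 3.14 and Gchfr, the feedback regulator of GTP cyclohydrolase, by 3.10. Further rises were those of Deptor, an inhibitor of mTOR (8.02-fold), the small heat shock protein Cryab (log2 change 2.90), the lysosomal iduronate sulfatase Ids (2.85) and the cholesterol ester hydrolase Nceh1 (2.54). The matrix proteoglycan Omd and Ier5l rose by 2.49 and 2.45. In the other direction, the signalling adaptor Dok2 fell by 4.32, from 12.66 ± 2.26 to 8.35 ± 1.67 (SD, n = 3). The membrane mucin Muc1 fell by 2.83, the tissue plasminogen activator Plat by 2.74, the transcriptional cofactor Eya2 by 2.72 and Gatm, an enzyme of creatine synthesis, by 2.72. Dhh (desert hedgehog) fell by 2.62, Fxyd3, a regulator of the sodium pump, by 2.44, and Sigirr, an inhibitor of interleukin-1 receptor signalling, by 2.35. The acyl-CoA synthetase Acsbg1 and the apolipoprotein Apob fell by 2.29 and 2.16. The tight junction gene Cldn6 had a change of -2.14 and just missed the threshold (adjusted p = 0.0515), and in the fit without the block it was 0.49 without the KO array of B1. Within the lines its change was -2.34 in B1, -1.70 in B2 and -2.38 in B11. Its control level was 6.68 in B1 against 14.27 in B2 and 14.29 in B11, so the 0.49 reflects the unbalanced B1 pair. The calls above come from limma with the cell line as a block. In that fit 30 of 19505 genes passed, 19 higher and 11 lower, each at an adjusted p of 0.0477. Without the block limma called 0 genes (lowest adjusted p = 0.256, 1319 genes at an unadjusted p under 0.05, of which 714 were higher), and with the line as a random block it called 7, 3 higher and 4 lower. The 30 calls ended under quantile normalization (0 genes, lowest adjusted p = 0.0506), cyclic loess (0 genes, lowest adjusted p = 0.0554) or without the B1 pair (0 genes), and rose to 102 without the B2 pair and 72 without the B11 pair.

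**Figure D2:**
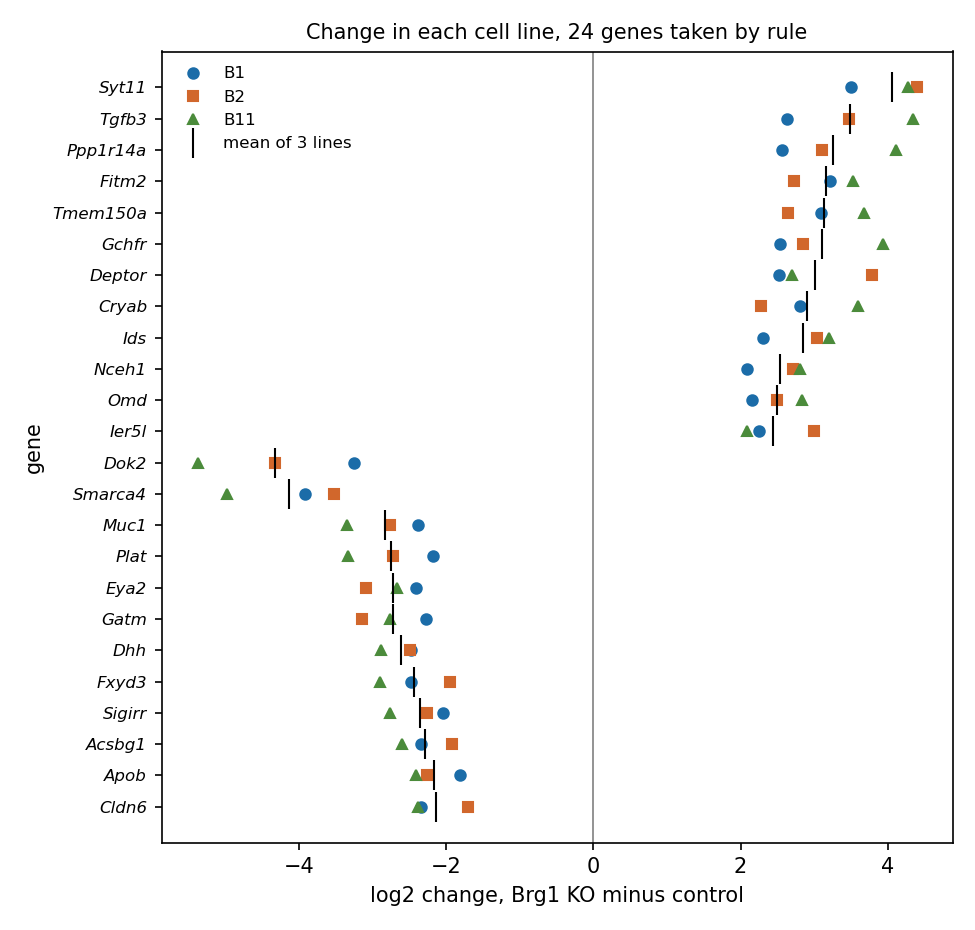
Log2 change, Brg1 KO minus control (horizontal axis), of 12 rises and 12 falls taken by rule (vertical axis). Each gene has 1 symbol per cell line and a black bar for the mean of the 3 lines. The rule took the largest changes among genes past the threshold with the line as a block, and Cldn6 by its low p without passing. Larger changes that did not pass, such as that of Mmp13 (-5.19), are not shown. The 3 lines lie on the same side of 0 in every gene because the rule required it, and the means run from -4.32 for Dok2 to 4.06 for Syt11.

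Among the gene lists fixed in advance, genes known to be induced by hypoxia fell as a group by limma's camera with its preset correlation, by a mean of -0.65 over 56 measured members (adjusted p = 3.44e-06, but adjusted p = 0.583 with an estimated correlation). Of the members, 43 were lower on the mean of the 3 lines and 18 were lower in all 3. The group went down in B1 (mean -0.82) and B11 (-1.53), and up in B2 (0.42). Among the members with an even direction, the log2 change was -1.58 for the hexokinase Hk2, -2.36 for the metallothionein Mt2 and -1.46 for the growth factor Tgfa, and 2.73 for heme oxygenase Hmox1, which is also a target of the oxidative stress factor NRF2. The lactate exporter Slc16a3, named after its values were seen, was at -5.55 in B1, 0.67 in B2 and -6.67 in B11, and Vegfa, also named afterwards, at -1.65, 0.05 and -2.38. Of the 56 members, 0 passed when adjusted over the list alone, with or without the block, and 0 over all genes. Glycolytic enzymes and transporters, which share 16 members with the hypoxia list, fell by a mean of -0.58 over 19 members (camera adjusted p = 6.16e-04, but adjusted p = 0.583 with an estimated correlation). Their means were -0.73 in B1, 0.16 in B2 and -1.17 in B11. Adjusted over the list alone with the line as a block, 4 of them fell: Hk2, the glucose transporter Slc2a1 (-1.15) and, named after their values were seen, Tpi1 (-0.86) and Ldha (-0.71). Without the block 0 passed when adjusted over the list alone. The HIF subunits and their regulators as a group did not pass (13 members, mean -0.31, camera adjusted p = 0.373). Of them 1, the circadian repressor Bhlhe41, fell by 2.34 when adjusted over the list alone with the block. The oxygen sensor Egln1 was at -1.11. The HIF list passed without the control array of B2 (mean -0.55, adjusted p = 0.0336). Both list calls ended without the control array of B11 (mean -0.16, adjusted p = 0.0566, and mean -0.20, adjusted p = 0.0549), and glycolysis also in the block fit without the B11 pair (mean -0.28, adjusted p = 0.0554). Without the B11 pair the hypoxia mean was -0.20, and without the control array of B2 the means were -1.18 for hypoxia and -0.97 for glycolysis (-1.18 and -0.95 without the B2 pair).

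Markers of the pancreatic duct and of the gastric or classical type of pancreatic cancer fell as groups by camera (adjusted p = 0.00247 and 6.16e-04, but adjusted p = 0.583 for each with an estimated correlation), with means below 0 in each of the 3 lines. The duct list had a mean of -0.98 over 10 members, with B1 at -0.86, B2 at -0.55 and B11 at -1.53. Adjusted over the list alone with the line as a block, 6 of the 10 fell, among them the water channel Aqp1 (-3.38), the chloride channel Cftr (-2.26), the transcription factor Sox9 (-2.05) and the keratin Krt7 (-1.65), and 1 rose, the carbonic anhydrase Car2 (2.69). Without the block 2 fell when adjusted over the list alone, Muc1 and Sox9. The gastric and classical list had a mean of -0.97 over 25 members, with B1 at -0.72, B2 at -0.52 and B11 at -1.68. In it, 7 members fell with the block when adjusted over the list alone, led by Anxa10 (-4.17), the gastric protease Ctse (-3.89), the trefoil peptide Tff1 (-3.89) and Muc1, and 2 rose, the transcription factors Pdx1 (1.09) and Gata4 (0.72), named after their values were seen. Anxa10 went from 13.64 ± 0.57 to 9.47 ± 1.28 (SD, n = 3). Without the block 2 of the 25 fell when adjusted over the list alone, Anxa10 and Muc1. The duct call ended without the KO array of B1 (mean -0.51, adjusted p = 0.108). The duct mean was -1.51 without the control array of B1 and -0.32 without the control array of B11. The gastric mean was -0.62 without the KO array of B11 or the B11 pair and -1.52 among bright genes only.

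Genes of epithelial adhesion and identity did not pass without the line as a block (28 members, mean -0.28, camera adjusted p = 0.266) and passed with it (adjusted p = 0.0107, but adjusted p = 0.638 with the block and an estimated correlation). Without the block, the mean was 0.065 without the control array of B2 and 0.0030 without the KO array of B1, and the list passed without the control array of B1 (-0.70, adjusted p = 0.0381), the KO array of B2 (-0.62, 0.0486) or the B1 pair (-0.41, 0.0239). Krt7 and the adhesion molecule Epcam (-1.48) fell and P-cadherin, Cdh3 (2.32), rose when adjusted over the list alone with the block, while the protease St14 was at -1.24 without passing. The mesenchymal list did not pass (26 members, mean -0.23, adjusted p = 0.341). In it the receptor Axl fell by 1.94 and N-cadherin, Cdh2, rose by 0.92 in the block fit adjusted over the list alone. The transcription factor Twist1 was at -0.55 and lower in each line (-0.66 in B1, -0.31 in B2 and -0.68 in B11). Without the KO array of B1, which left that pair unbalanced, it was at 0.41. Stem cell and cancer stem cell markers did not pass as a group either (26 members, mean -0.33, adjusted p = 0.266). Of these, 5 fell in the block fit adjusted over the list alone, Aldh1a3 (-2.45), Sox9, the filament gene Nes (nestin, -1.74), Epcam and Cd44 (-1.24), and 1 rose, the receptor Met (0.86); Cd44 and Met were named after their values were seen, and 0 passed without the block. Aldh1a1 was at -1.69. The list passed once the B2 pair was left out (mean -0.52, adjusted p = 0.0188). Matrix proteases and invasion genes did not pass as a list (22 members, mean -0.48, adjusted p = 0.265), but 3 members fell with and without the block when adjusted over the list alone. These were the collagenase Mmp13, from 10.29 ± 1.52 to 5.10 ± 1.25 (SD, n = 3), Plat, and the inhibitor Timp1 (-1.46), named after its values were seen. Mmp10 was at -1.60 and Adamts1 at 1.54.

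Mitotic genes fell as a group by camera (adjusted p = 2.6e-13, but adjusted p = 0.583 with an estimated correlation). They were lower in 39 of 39 measured members, by a mean of -0.82, with B1 at -0.13, B2 at -1.76 and B11 at -0.57. The spindle checkpoint kinase Bub1b (-1.48), the ubiquitin-conjugating enzyme Ube2c (-1.47) and the centromeric histone Cenpa (-1.45) fell when adjusted over the list alone with the block, Cenpa also without it, and the kinesin Kif2c was at -1.43. Genes of DNA replication and S phase also fell (camera adjusted p = 2.18e-07, but adjusted p = 0.583 with an estimated correlation). In this list 32 of 32 members were lower, with a mean of -0.62, made up of -1.72 in B2, -0.10 in B1 and -0.05 in B11. Gins1 was at -1.24, the ribonucleotide reductase subunit Rrm2 at -1.10, Pole at -0.99 and Gins2 at -0.96, and 0 members passed when adjusted over the list alone. The S phase call ended without the control array of B2 (mean -0.15, adjusted p = 0.0752) and without the B2 pair (mean -0.07, adjusted p = 0.34), and its mean was -0.94 without the control array of B11. The mitotic mean was -0.34 without the control array of B2 and -0.35 without the B2 pair. Genes of ribosome biogenesis did not pass as a list (24 members, mean -0.12, camera adjusted p = 0.437) and were at -0.93 in B2, 0.14 in B1 and 0.43 in B11. That list passed downward without the control array of B1 (mean -0.39, adjusted p = 0.0152), the control array of B11 (-0.34, 0.0426) or the B11 pair (-0.40, 0.0164). It passed upward without the control array of B2 (0.35, 0.0047) or the B2 pair (0.28, 0.021), and its mean was 0.012 without the KO array of B1. Genes activated by p53 did not pass as a group (22 members, mean 0.24, adjusted p = 0.265). Adjusted over the list alone with the line as a block, 4 of them rose, Btg2 (2.31), Sesn1 (1.09), Rrm2b (0.94) and, named after its values were seen, Ccng1 (0.68), and Plk3 fell by 1.10.

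YAP/TAZ target genes were the list that rose by camera, by a mean of 0.61 over 22 members (adjusted p = 0.0014, but adjusted p = 0.583 with an estimated correlation). Of them 17 were higher, with B1 at a mean of 0.51, B2 at 0.51 and B11 at 0.82. The medians over members were 0.54 in B1, 0.10 in B2 and 0.99 in B11. The stress gene Gadd45a rose from 9.02 ± 0.77 to 12.13 ± 0.88 (SD, n = 3) and passed adjusted over the list alone with and without the block. Adjusted over the list alone with the block, Tgfb2 (1.52) and Ptpn14 (1.47), named after their values were seen, also rose, and Axl and the ectonucleotidase Nt5e (-2.16) fell. The matricellular gene Ccn1 was at 2.34. Output genes of the ERK pathway fell by a mean of -0.39 over 15 members (camera adjusted p = 0.00955, but adjusted p = 0.583 with an estimated correlation). In the block fit adjusted over the list alone, 5 fell and 2 rose. Adjusted in this way, the transcription factors Etv4 (-1.71) and Fosl1 (-1.54) fell with and without the block, the phosphatase Dusp4 (-1.26) fell with it, and the feedback inhibitor Spry1 (1.02) rose with it. Genes of cholesterol synthesis and uptake fell by a mean of -0.62 over 19 members (camera adjusted p = 2e-04, but adjusted p = 0.583 with an estimated correlation). Their means were -0.34 in B1, 0.12 in B2 and -1.65 in B11. Insig1 was at -1.86, Nsdhl at -1.19, Fdft1 at -1.19 and Lss at -1.11, and 0 members passed when adjusted over the list alone. Genes often used as references fell as well (camera adjusted p = 0.00102, but adjusted p = 0.583 with an estimated correlation). Of them 9 of 9 measured members were lower (mean -0.38). The transferrin receptor Tfrc (-1.10) and the glucuronidase Gusb (-0.83) fell with and without the block adjusted over the list alone. The mean of the reference genes was close to that of the ERK list (-0.39), so a fall of that size was not particular to ERK output genes. The cholesterol call ended without the B11 pair (mean -0.11, adjusted p = 0.459), and its mean was -0.39 without the control array of B11, -0.34 without the KO array of B11 and -0.99 without the B2 pair. The ERK call ended without the control array of B11 (mean -0.37, camera adjusted p = 0.0537) or the KO array of B1 (-0.28, 0.13). It also ended without the B1 pair (-0.34, 0.0677) or the B2 pair (-0.35, 0.0566).

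**Figure D3:**
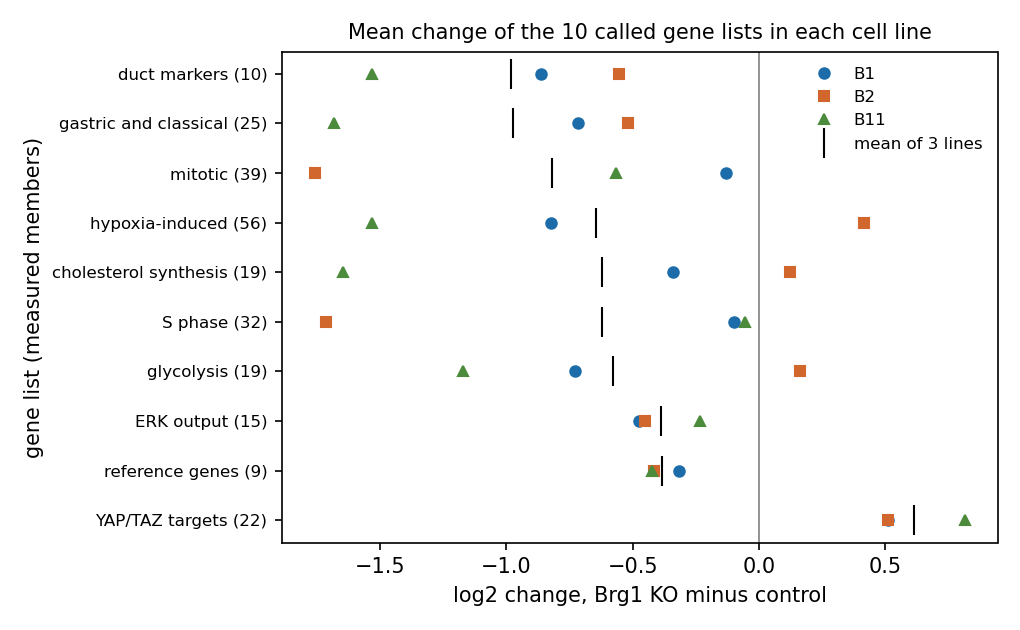
Mean log2 change, Brg1 KO minus control (horizontal axis), of the measured members of the 10 gene lists that passed camera with its preset correlation (vertical axis, number of members in brackets), with 1 symbol per cell line and a black bar for their mean. Duct, gastric, ERK, reference and YAP/TAZ genes lie on the same side of 0 in all 3 lines, whereas hypoxia, glycolysis and cholesterol genes lie above 0 in B2, at 0.42, 0.16 and 0.12.

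Other groups did not pass as lists but held members that passed when adjusted over the list alone. Among SWI/SNF subunits (27 members, mean 0.02, camera adjusted p = 0.458), Smarca4 (-4.14) fell and Bicral (1.23), Arid1b (1.19) and Arid2 (0.91) rose in the block fit adjusted over the list alone. MHC class I presentation genes had a mean of 0.40 over 11 members (adjusted p = 0.0757), and Tapbp (1.61), B2m (1.34) and Erap1 (1.24) rose in the block fit adjusted over the list alone, Erap1 also without the block. That list passed without the control array of B11 (mean 0.63, camera adjusted p = 0.0143) or the KO array of B2 (0.50, 0.0453). It also passed without the B11 pair (0.46, 0.0311) and with a random block (0.40, 0.0333). Interferon-stimulated genes had a mean of 0.19 over 36 members (camera adjusted p = 0.335). Among bright genes only, the mean of that list was 0.68 (camera adjusted p = 0.035). Ifih1 (1.98) and Irf9 (1.42) rose with the block adjusted over the list alone, as did Xaf1 (1.25), named after its values were seen, while Usp18 and Cxcl10 were at 1.90 and 1.37. NRF2 targets had a mean of 0.39 over 17 members (adjusted p = 0.266), with B2 at 1.74, B1 at -0.11 and B11 at -0.45. In the block fit adjusted over the list alone 4 of them rose, Srxn1 (3.41), Hmox1, the glutathione transferase Gsta4 (1.61) and, named afterwards, Txnrd1 (0.79), and Osgin1 (-1.02), also named afterwards, fell. Gclm was at 1.09. Drug metabolism and aryl hydrocarbon receptor genes had a mean of 0.17 over 11 members (adjusted p = 0.866, with camera's direction down against a positive mean), in which, adjusted over the list alone, the cytochrome Cyp1b1 rose by 4.17 with the block and the drug efflux pumps Abcb1a (-1.71) and Abcb1b (-1.52) fell with and without it. Estrogen-response genes had a mean of -0.42 over 12 members (adjusted p = 0.437), with Tff1 falling in the block fit adjusted over the list alone and Nrip1 and Esr1 at -0.80 and 0.79. The NRF2 list passed, upward, without the control array of B1 (mean 0.83, adjusted p = 0.0461), the KO array of B11 (0.83, 0.00113) or the B11 pair (0.81, 0.00657) and had a mean of -0.28 without the B2 pair.

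Markers of other cell types that a tumour-derived culture could hold did not differ past the threshold. Fibroblast markers had a mean of -0.15 (17 members, camera adjusted p = 0.266), leukocyte markers -0.08 with a median of 0.014 (16 members, 0.814), acinar markers 0.05 (15 members, 0.867) and islet markers 0.08 (15 members, 0.595). Endothelial markers (12 members) had an adjusted p of 0.92, a median of -0.011 and an upward camera direction, and their mean level was 3.93 in both groups. The mean levels in control cells were 4.49 for fibroblast, 4.49 for leukocyte, 3.90 for acinar and 3.92 for islet markers, close to the lower quartile of the arrays, which lay between 3.87 and 3.96. Cd14, a leukocyte marker, was an exception with 13.35 ± 0.65 in control and 11.87 ± 1.23 in KO cells (SD, n = 3), as was Fbln1 of the fibroblast list with 10.12 ± 1.38 and 9.05 ± 0.80.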

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

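Several results went one way in B1 and B11 and the other way in B2, each by at least 0.1 on the log2 scale; these differences between lines were not tested, since each line has 1 array per group. The tests of normalization and of the control cultures were chosen after the result was seen. The hypoxia list had a mean change of 0.42 in B2 against -0.82 in B1 and -1.53 in B11. Glycolysis genes were at 0.16 in B2 against -0.73 and -1.17, and cholesterol genes at 0.12 against -0.34 and -1.65. Immediate early genes were at 0.40 in B2 against -0.12 in B1 and -0.13 in B11, and ribosome biogenesis genes at -0.93 in B2 against 0.14 and 0.43. NRF2 targets were at 1.74 in B2 against -0.11 in B1 and -0.45 in B11, Smarca2 at 0.89 against -0.19 and -0.13, and Hif1a at 0.21 against -0.42 and -0.96.

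For the hypoxia list, an intensity-dependent difference between arrays is argued against as the whole cause, because after cyclic loess the mean over B1 and B11 was -1.22 with an SE over members of 0.18, against -1.18 as deposited. The control arrays differed in the mean level of the list by 2.05, from 9.96 in B2 to 11.13 in B1 and 12.01 in B11, while the 3 KO arrays lay within 0.17 of each other, between 10.31 and 10.48. The fall in B1 and B11 may therefore reflect how hypoxic or dense their control cultures were, or a Brg1-dependent part of the hypoxia response that B2 cells did not use; with 1 control culture per line these cannot be told apart. A weaker deletion of Brg1 in B2 also stays open, as Smarca4 was lowered least there (-3.52, against -3.91 in B1 and -4.98 in B11). It would act on the KO array, however, and would not account for the low list level in the B2 control. In B2 1146 genes were at least 2-fold higher and 1040 lower, against 458 and 653 in B1 and 1208 and 1424 in B11. Outside the hypoxia and glycolysis lists, 659 genes moved at least 2-fold the same way in B1 and B11. Of these, 85.6% went the same way in B2, against 5 of 20 hypoxia genes chosen alike. Their median change in their direction was 1.03 in B2, 1.44 in B1 and 2.09 in B11. Choosing genes by their size in B1 and B11 favours a lower median in B2, so these medians do not bear on the deletion. Comparing the shares, as planned beforehand, was the wrong test. The hypoxia list was weighed for going the other way in B2, which fixes its lower share. The comparison therefore says nothing about a weaker deletion.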

How the results depend on the processing

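Cyclic loess and the combinations with the block were chosen after seeing the data. Without the block, limma called 0 genes under each alternative run; with the replicate block it called 30, and with a random block 7. That count of 30 went to 0 with quantile normalization, 0 with cyclic loess, 59 with bright genes only, 67 with trend and robust variance and 418 at an adjusted p under 0.1, and lay between 0 and 102 when a pair was left out; 29 and 30 of the 30 genes were among the 59 and 67. It was 30 with median centring (28 shared) and with the mean of probe sets (30 shared). The quantile and cyclic loess counts ended because the lowest adjusted p moved from 0.0477 to 0.0506 and 0.0554. Smarca4 stayed at -4.14 and passed with the replicate block, but did not pass with a random block (limma adjusted p = 0.0722). Over left-out arrays and pairs its change lay between -4.93 and -3.65. In the block fit it passed without the B2 or the B11 pair, but not without the B1 pair (limma adjusted p = 0.179). The 10 called lists became 11 with the replicate block, which added the epithelial list and changed no other list call, 0 with an estimated correlation and 1 with fry (reference genes, adjusted p = 0.0114), and lay between 8 and 14 when an array or pair was left out. The 10 lists kept their direction in all settings run.

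Reversed directions concerned values that did not pass as reported. Cldn6 and Twist1 were lower in each line, and reversed where the KO array of B1, their lowest, was left out without the block. The remaining arrays were then unbalanced between lines of unlike level, which accounts for both reversals. For the others the cause was not tested. With cyclic loess the SWI/SNF list had a mean of -0.019, and with bright genes only the endothelial and acinar lists had means of 0.29 and -0.17; the islet list then had no member left and no value. Over left-out arrays and pairs, means ranged from -0.068 to 0.061 for the endothelial list, from -0.048 to 0.070 for SWI/SNF, from -0.70 to 0.065 for the epithelial list, from -0.28 to 0.83 for NRF2 targets from -0.19 to 0.41 for the drug metabolism list, from -0.40 to 0.35 for ribosome biogenesis and from -0.13 to 0.28 for immediate early genes. Smarca2 ranged from -0.25 to 0.59, Epas1 from -0.85 to 0.29, Twist1 from -1.46 to 0.41 and Cldn6 from -4.67 to 0.49. The other named genes kept their direction in all settings run, and 82 of their values passed only under an alternative, mostly with the block. No detection limit came with the values, so changes of genes near the lower quartile of about 3.9 are the least certain.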

Other observations

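The tests of the cell cycle pattern were chosen after the result was seen, and the lysosomal list was written after Ids and other lysosomal genes had been seen.

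Inflammatory genes under NF-kB went both ways (28 members, mean -0.24, camera adjusted p = 0.582). In the block fit adjusted over the list alone, 5 members fell, among them the chemokine Cxcl5 (-2.36), the cytokine Lif (-2.19), the cyclooxygenase Ptgs2 (-2.17) and Traf1 (-1.29), and 4 rose, of which Nfkb2 (1.27) and Relb (1.19), named after their values were seen, also rose without the block. Among Notch genes (12 members, mean -0.22, median 0.019, adjusted p = 0.576), adjusted over the list alone, Nrarp fell by 1.94 with and without the block and the ligand Jag1 by 1.13 with it. Amino acid response genes had a mean of -0.33 over 15 members (adjusted p = 0.266, and 0.0132 with a mean of -0.61 without the control array of B2), with the serine synthesis enzyme Phgdh falling by 1.84, adjusted over the list alone with and without the block, and Psat1 at -1.01. Fatty acid synthesis genes had a mean of -0.45 over 11 members (adjusted p = 0.126, and 0.0302 in the block fit without the B2 pair) and TGF-beta responsive genes one of 0.32 over 13 members (adjusted p = 0.437), in which Smad6 rose by 1.77 with the block adjusted over the list alone. Immediate early genes went both ways, with a mean of 0.05, a median of -0.12 and a downward camera direction over 17 members (adjusted p = 0.595). Adjusted over the list alone with the block, Btg2, Nr4a1 (2.04) and, named after its values were seen, Jun (0.77) rose, and Fosb (-1.07) and Ier3 (-0.97) fell. The other 5 lists had means between -0.20 and -0.0010 and adjusted p between 0.392 and 0.902. Of 2634 unnamed probe sets, 0 passed in limma with the block over every probe set, where 30 probe sets passed in all; 294 unnamed ones had an unadjusted p under 0.05.

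For the cell cycle genes, which were lowest relative to control in B2, an intensity-dependent difference between arrays is argued against, since the mitotic list in B2 was at -1.73 after cyclic loess and -1.76 as deposited. The B2 pair accounts for the S phase call, which ended over B1 and B11 (mean -0.075, camera adjusted p = 0.274 with the block). Whether it also accounts for the mitotic list stays open: over B1 and B11 the mean was -0.35, with an adjusted p of 3.11e-04 with the block and the preset correlation and 0.70 with an estimated one. The mitotic level was 12.70 in the B2 control against 11.19 and 11.35 in the other controls, and between 10.78 and 11.06 in the KO arrays. A faster-growing B2 control culture and a slower cycle after Brg1 loss both stay open, and neither was tested.

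The rise of Ids led to the hypothesis that lysosomal genes are higher as a group after Brg1 knockout; Gusb, which had been seen to fall, and the genes seen to rise were left out of the test. Of 42 further lysosomal genes written down before their values were looked up, 37 were measured, with a mean of 0.40 ± 0.46 (SD over genes); 30 were higher, 20 of them in all 3 lines and 2 lower in all 3. Camera gave p = 0.00146 with the preset correlation, 1.59e-05 with the block and 0.422 with an estimated correlation, and the means were 0.13 in B1, 0.64 in B2 and 0.41 in B11. A rise of lysosomal genes may belong to the response, but genes seen on these same arrays prompted the list. Members moved together (estimated correlation 0.45), so the test is not independent of what had been seen. The drug 4-hydroxytamoxifen could also act on lysosomes directly, and the design has no array that separates it from the deletion.

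With 3 arrays per group, the 4 splits that part all 3 pairs are too few for a share under 0.05. Without the block the real split gave 0 genes and the highest other split 0, so 4 of 4 splits were as large; with the block it gave 30 genes, the highest other 0, and 1 of 4 splits was as large. For the lists called by camera the real split gave 10 and the highest other 12, so 2 of 4 were as large. That split exchanges the 2 arrays of B2, the line in which the hypoxia and cell cycle lists stood apart. The remaining 6 of the 10 splits keep 2 pairs together and gave between 3 and 11 lists.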
